A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

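RNA of a ura3 deletion strain of Halobacterium salinarum NRC-1, a halophilic archaeon, was hybridised to spotted 2-colour arrays. There were 4 RNA samples, 1 for each combination of oxygen and light. Per the labels' protocols, 50 mL cultures in 125 mL flasks were shaken at 210 rpm for high oxygen, the low-oxygen flasks were shaken at 100 rpm, and dark flasks were painted. Each RNA sample was hybridised to 2 arrays as a dye flip, with the sample in Alexa 532 on replicate 1 and in Alexa 647 on replicate 2, against a common NRC-1 reference RNA in the other dye. The labels describe the reference as mid-log cells and give neither its oxygen level nor its light. The 2 arrays of a sample are technical replicates and were averaged to 1 value, which leaves 4 values and 1 RNA sample per condition. All p-values therefore measure the spread among these 4 samples and not among separate cultures of a condition.

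The deposited scanner tables give, per the file headers, the spot and background intensity of each dye at 2 scanner settings, with a spot confidence in percent. The authors applied no background subtraction or normalization to these intensities, as far as the headers show. The scanner and the quantification software are not given in the sources used here. Confidence was below 100 percent only where the brightest pixel stood at the scanner limit, so it marks saturation. The authors' deposited value table holds log10 ratios. Set against the scanner intensities in raster order, 79.0% to 89.6% of the values that were not exactly 0 equalled log10 of Alexa 532 over Alexa 647, without background subtraction, plus 1 constant per array, within 0.001. Dye flips were not turned in that table. Its column medians were 0.109 and 0.043 for high oxygen in light, 0.024 and 0.090 for high oxygen in dark, 0.057 and 0.075 for low oxygen in light, and 0.080 and 0.016 for low oxygen in dark. How the authors set the constants and the remaining values is unknown. In 7 columns 2309 rows had no value, and the column of low oxygen in dark replicate 2 had none missing and 1558 exact zeros. Where the authors' table is used below, exact zeros were kept as ratios. Each array was then only centred on its median.

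The array holds 10752 spots at 2688 positions of 4 spots each. The 93 positions at which none of the 4 spots had a value in those 7 columns were treated as blanks, given weight 0 in the normalization and left out, so that 2595 positions, called genes here, were tested. The probe table pairs 532 probes with 1 gene symbol, no probe with several and 10220 with none. This names 133 genes. The other 2462 are unnamed here and are given by the number of their first probe. The annotation table at hand was of another strain and was not used, and no genome coordinates are given.

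Spot mean intensities of the high scanner setting were corrected with limma's normexp (offset 50) on the background median, normalized by global loess within each array, turned to sample over reference and averaged over the 4 spots. The high setting, the spot mean and the keeping of saturated spots were chosen after the scanner tables, and correlations between arrays under several settings, had been examined. limma 3.58.1 in R 4.3.3 fitted an intercept (cultures against the reference), an oxygen term and a light term to the 4 values. This leaves 1 residual degree of freedom, which is the oxygen by light interaction, beside 2.00 prior degrees of freedom from eBayes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and against the reference also at an absolute log2 ratio of at least 1. The interaction has no test. Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 measured genes. Of 24 lists fixed before the data were examined, 15 had a named gene and 9 could be tested, and 7 further lists were written after the gene names, and the authors' values of a few genes, had been seen. An estimated correlation rests on 1 residual degree of freedom here and takes degenerate values, so a list could hardly pass with it. Values given with it do not weigh for or against a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

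The rule for named genes, fixed before the data were examined, took per comparison the called genes with the largest changes or, where none was called, the 5 smallest p in each direction, and in any case a set of genes of which pyrF, bat, hop, arcA and arcC were measured. For the interaction it took the 5 largest values of each sign among brighter genes whose dye orientations had the same sign. As nearly all genes with the smallest p were unnamed, the 5 smallest p in each direction among genes with a symbol were added, and likewise 4 genes with a symbol per sign of the interaction. These additions were chosen after the values of the named genes had been seen. Members of lists quoted as examples were also chosen after their values were seen. Several combinations of background correction, normalization and gene filter were looked at before the correlation of oxygen effects in brighter genes was chosen for a closer look.

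The fit was tested on simulated data with 200 of 2595 genes changed. A log2 change of 1 was called for 0% of the changed genes in either comparison, although 95% of them for oxygen and 90.5% for light had an unadjusted p below 0.05. A log2 change of 2 was called for 94% (oxygen) and 92% (light). Of 205 genes called for oxygen 188 had been changed, and of 192 for light 184. Each setting was simulated once, with noise independent between genes, drawn from the fitted variance prior, and a dye effect shared by all samples. The data depart from this, as correlated neighbouring positions and unlike dye effects show below. The rates therefore hold under the model's own assumptions, and recovery in the data may be lower. The fit rests on 4 RNA samples. Alternatives fixed before the data were examined were the background correction, median centring, print-tip loess, between-array scaling, the median of spots, leaving out dim genes or saturated spots, a variance trend, a fit of all 8 arrays with a dye term and the sample as a random block, the authors' table, an adjusted p below 0.10, and each array left out in turn. Added after the data had been seen were low-setting ratios for saturated spots, only brighter genes without a saturated spot, leave-one-out fits with the dye effect removed, and removal of the median of each row of a print block. This last correction was 1 of 6 for position on the array, picked because it lowered the correlation between neighbouring positions most. It may also remove a shared response of genes placed near each other. The directions of the lists under each normalization, camera with an estimated correlation under the alternatives, the correlation of dye effects between samples and the exchange of the dye of 1 array were added last.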

Results

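The experiment measured transcripts of a ura3 deletion strain of the halophilic archaeon Halobacterium salinarum NRC-1 at 2 oxygen levels, in light and in dark. Each of the 4 RNA samples was hybridised to 2 arrays with the dyes flipped, against a common NRC-1 reference RNA. Median spot intensities ranged from 2015 to 8650 in Alexa 532 and from 2476 to 12187 in Alexa 647, and median local backgrounds from 550 to 2777 and from 398 to 1784 or, on the replicate 2 array of low oxygen in dark, 2046. Between 4.03% (high oxygen in light, replicate 1) and 20.6% (low oxygen in light, replicate 1) of the spots held saturated pixels. The dye flips of 1 sample correlated across genes, after turning, at 0.20 for high oxygen in light, -0.23 for high oxygen in dark, -0.34 for low oxygen in light and -0.02 for low oxygen in dark. Arrays of different samples in the same dye orientation correlated at 0.25 on average, over a range from -0.25 to 0.50. Replicate 1 of high oxygen in light stood apart: its 3 pairs averaged -0.11 and the other 9 averaged 0.37, and the SD of its gene log2 ratios was 0.61, against 0.30 to 0.45 on the other arrays. Genes are not independent replicates. All values below are log2 ratios from the means of dye flips, with the standard error (SE) of the limma fit over 4 RNA samples (n = 4), unless stated otherwise.

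The ura3 gene, named pyrF on the array, encodes orotidine 5'-phosphate decarboxylase of pyrimidine synthesis. Its log2 ratio to the reference was -0.05 in high oxygen and light, -0.09 in high oxygen and dark, -0.27 in low oxygen and light and 0.04 in low oxygen and dark. The mean was -0.09 ± 0.07 (SE, limma adjusted p = 0.559), with 3 of 8 arrays above 0. On the arrays of high oxygen in light the values were 0.67 and -0.77, so that the dye orientations differed by more than the samples did. In the sample channel the pyrF spots measured from 1163 (local background 536) to 6343 (background 1552). The spots were near background on 4 arrays, and measured 3136 (background 1913) in low oxygen and dark, replicate 1. Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so this value does not check the labels.

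The series title names the ura3 deletion, which the comparison with the reference addresses. The reference is a single RNA whose own spread was not measured, and its oxygen and light are not given. The SE and p against it leave out that spread. An effect of the deletion therefore cannot be told apart from other differences between the cultures and the reference. Among named genes below the reference, the smallest p belonged to phoU, rpl12p, gdhA2, hemA and purL. The ratio of phoU, a regulator of phosphate uptake, was -0.50 ± 0.06, that of rpl12p, a ribosomal protein gene, -0.40 ± 0.06, that of purL of purine synthesis -0.34 ± 0.07, that of gdhA2, a glutamate dehydrogenase gene, -0.32 ± 0.05, and that of hemA of tetrapyrrole synthesis -0.28 ± 0.05. All of them had an adjusted p of 0.388 and were not called. The ratio was below 0 on 8 of 8 arrays for phoU, rpl12p, hemA and purL, but for gdhA2 on 6. The spots of rpl12p were saturated on 7 arrays and those of phoU on 4, which leaves the size of their ratios uncertain. Among named genes above the reference, those with the smallest p were htr18, a transducer gene (0.22 ± 0.07), pan1, a proteasome-activating nucleotidase (0.21 ± 0.05, above 0 on 8 of 8 arrays), htr6, another transducer gene (0.20 ± 0.08), hop, the light-driven chloride pump halorhodopsin (0.18 ± 0.05), and aroC, chorismate synthase (0.18 ± 0.05), with adjusted p from 0.388 to 0.398. The values of bat, arcA and arcC were 0.13 ± 0.09, 0.03 ± 0.05 and 0.13 ± 0.06. With the median of each block row removed, gdhA2 stood at -0.16.

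Among the lists, 6 of the 7 measured purine synthesis genes were below the reference, with a median of -0.10 and a range from -0.34 to 0.00 (camera adjusted p = 0.0797; 0.728 as adjusted p with an estimated correlation). Of 6 genes of the TCA cycle, 5 were below it, with a median of -0.11 (adjusted p = 0.0797; 0.728 as adjusted p with an estimated correlation), among them sucC of succinyl-CoA ligase at -0.33 ± 0.06. Of 7 halobacterial transducer genes 5 lay above the reference (median 0.11, adjusted p = 0.162), and 4 of 4 chemotaxis genes did (median 0.09, adjusted p = 0.165). Of 5 pyrimidine genes 4 lay below (median -0.07, adjusted p = 0.165), with carB of carbamoyl phosphate synthase at -0.21 ± 0.05. In every normalization tried at most 1 purine and at most 1 TCA gene lay above the reference, while 2 of 4 chemotaxis genes did with median centring and with the authors' table. With median centring the medians of pyrimidine synthesis (-0.18), the chaperones (-0.16) and cobalamin synthesis (-0.16) lay further below 0, and with block-row medians removed that of cobalamin synthesis was 0.01. DNA repair (1 of 4 above 0, median -0.04), cobalamin synthesis (1 of 4, median -0.02), the chaperones and proteasome (1 of 4, median -0.04) and the rhodopsins with their transducers (3 of 5, median 0.00) had an adjusted p from 0.545 to 0.826. Saturated on at least 4 arrays were 3 of 6 TCA, 2 of 4 chemotaxis, 2 of 5 pyrimidine and 1 of 7 purine genes. So were 3 of 4 cobalamin genes and 3 of 4 chaperone and proteasome genes, which leaves sizes in these lists uncertain in all comparisons. No list passed, and 0 genes were called in these 9 lists adjusted over the list alone. The lists of ribosomal proteins and phosphate transport had 1 measured gene each, rpl12p and phoU, for which the p adjusted over the list alone is the unadjusted p (0.00600 and 0.00444). Over all genes limma called 0 of 2595 against the reference, with 327 at an unadjusted p below 0.05 (172 above and 155 below the reference, about 129.8 by chance) and a smallest adjusted p of 0.388. Of the 133 named genes 21 had an unadjusted p below 0.05, of which 17 lay below the reference. The lists hold named genes only, while camera set them against all genes, which are mostly unnamed (median ratio to the reference 0.01). A difference of a list from the reference can therefore not be told apart from one of the named genes as a set. The unnamed gene at probe_4433 had the lowest ratio, -1.79 ± 0.11, below 0 on all 8 arrays. It was called with no background correction (-1.13, adjusted p = 0.00323), in the fit of 8 arrays with the sample as a random block (adjusted p = 0.00166), with the authors' table (-1.12, where phoU and rpl12p also had an adjusted p below 0.05) and without replicate 1 of high oxygen in dark (-1.89, adjusted p = 0.0291), while its adjusted p reached 0.627 among the other settings. The random-block fit called 146 genes without the limit on size, but its consensus correlation was -0.36, which lowers its errors.

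**Figure D1:**
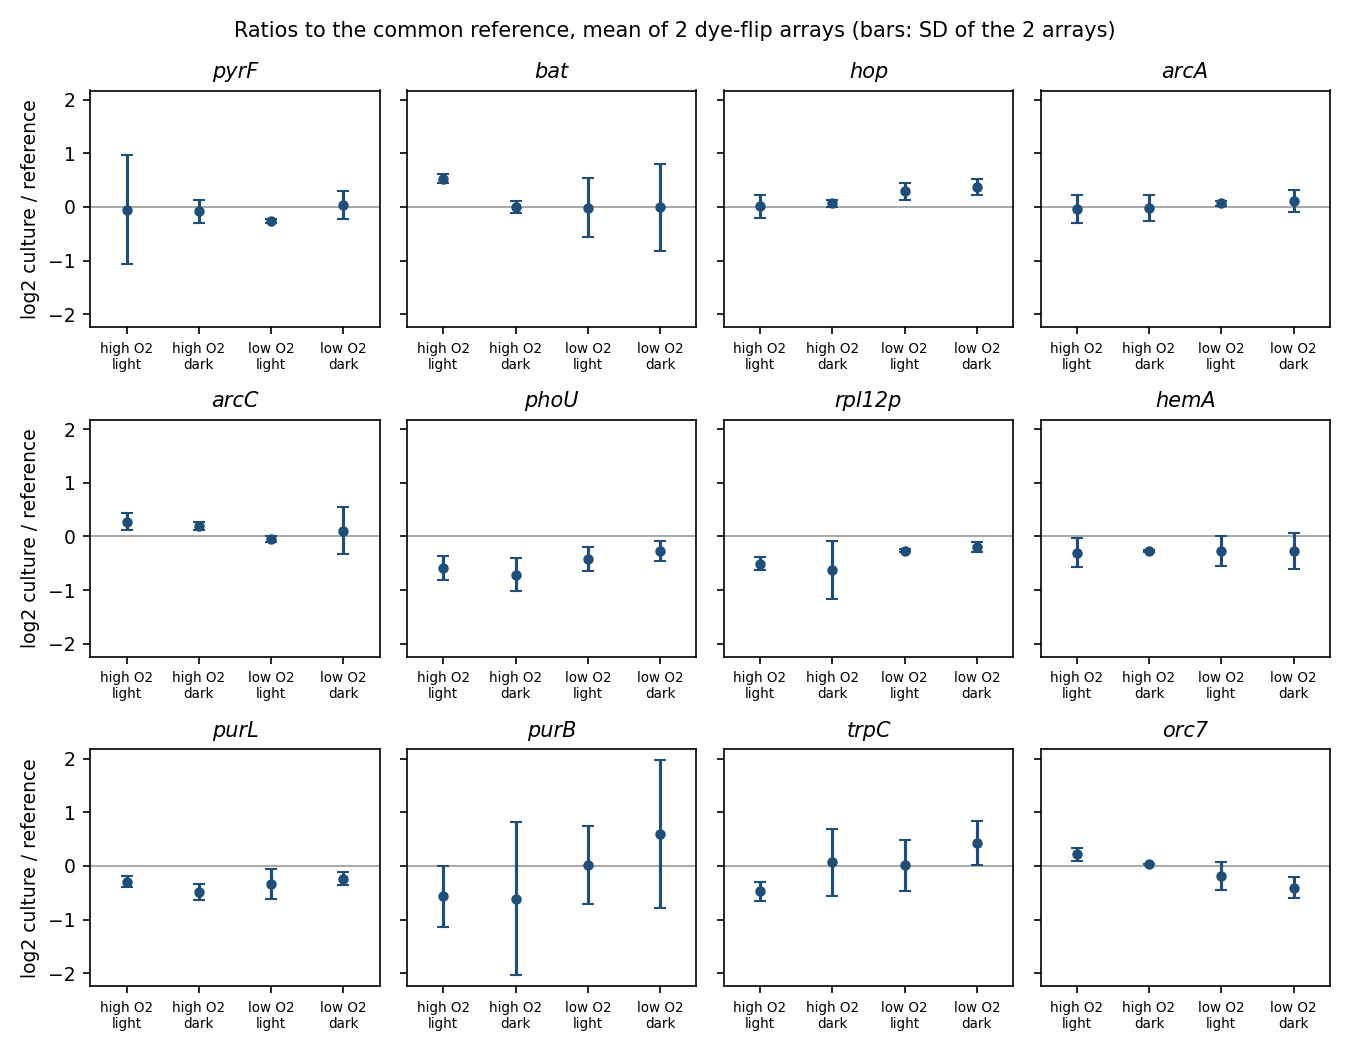
Log2 ratio of culture over reference (vertical axis) of 12 named genes in the 4 RNA samples (horizontal axis); points are means of 2 dye-flip arrays and bars the SD of the 2 arrays, which is technical. The ratios of phoU, rpl12p, hemA and purL lie below 0 in every sample, pyrF lies between -0.27 and 0.04, and bat stands apart at 0.52 in high oxygen and light.

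The next question was how oxygen changed transcripts. Among named genes, purB of purine synthesis had the largest value in low over high oxygen (0.89 ± 0.21), at 0.58 in light and 1.21 in dark, from spots near background on all 8 arrays. The values were 0.45 ± 0.12 for folP of folate synthesis, 0.42 ± 0.11 for trpC of tryptophan synthesis, 0.36 ± 0.11 for mutL of mismatch repair and 0.36 ± 0.11 for gdhA1, a glutamate dehydrogenase gene. In the other direction, orc7, of the Orc1/Cdc6 family of replication origin proteins, had -0.42 ± 0.10, with -0.40 in light and -0.43 in dark. The value was -0.54 ± 0.23 for hutU of histidine degradation, near background on 7 arrays, -0.21 ± 0.12 for arcC, carbamate kinase of arginine fermentation, -0.17 ± 0.10 for cheA, the chemotaxis kinase, and -0.16 ± 0.10 for carA. None was called: the adjusted p was 0.680 for purB, folP, trpC, mutL, gdhA1 and orc7 and between 0.734 and 0.781 for the other 4. With the median of each block row removed, folP stood at 0.09, trpC at 0.20, mutL at 0.22, purB at 0.54 and orc7 at -0.28, while arcC turned to 0.06.

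Of the genes named in advance, hop had a value of 0.29 ± 0.10 (0.28 in light and 0.30 in dark, adjusted p = 0.693), positive in 4 of 4 single-orientation estimates, but 0.03 with the median of each block row removed. The value of arcA, arginine deiminase, was 0.12 ± 0.10 (0.34 with the median of each block row removed, -0.04 with the authors' table), and that of bat, the activator of the bacteriorhodopsin genes, -0.27 ± 0.18. The arcA spots were saturated on 4 arrays and those of arcC on 5. The value of pyrF was -0.05 ± 0.14, but 0.09 with print-tip loess and 0.18 with the authors' table. All 7 purine synthesis genes had values above 0, with a median of 0.05 and a range from 0.00 to 0.89 (adjusted p = 0.425; 0.849 as adjusted p with an estimated correlation), but 4 of 7 with median centring and 3 of 7 with the authors' table. All 4 chemotaxis genes, cheA, cheB, cheR and cheY, lay below 0 (median -0.13, adjusted p = 0.496), but 2 of 4 with median centring and 3 of 4 with print-tip loess or with block-row medians removed. The TCA cycle (4 of 6 above 0, median 0.07), the rhodopsins and their transducers (4 of 5 above 0, median 0.06), DNA repair (2 of 4 above 0, median 0.04) and cobalamin synthesis (2 of 4 above 0, median 0.06) each had an adjusted p of 0.587. All 4 cobalamin genes lay above 0 with median centring (median 0.10), the authors' table (0.10) and block-row medians removed (0.05), and the median of DNA repair was -0.02 with the authors' table, -0.03 with print-tip loess and -0.06 with block-row medians removed. With print-tip loess that of the TCA cycle was -0.01. The transducers (median -0.01, adjusted p = 0.921), pyrimidine synthesis (median -0.02, adjusted p = 0.980) and the chaperones and proteasome (median 0.00, adjusted p = 0.833) did not pass either. With median centring 3 of 4 chaperone and proteasome genes lay above 0 (median 0.19), 4 of 5 pyrimidine genes did with the authors' table (median 0.10), and with block-row medians removed 1 of 5 genes of the rhodopsins and their transducers did (median -0.03). Lists with too few named genes gave single values: 0.33 for rpl12p, 0.16 for nuoL of the NADH dehydrogenase-like complex and 0.30 for phoU. The spots of rpl12p and nuoL were saturated on 7 arrays and those of phoU on 4.

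limma called 0 of 2595 genes for oxygen, with 188 at an unadjusted p below 0.05 (87 higher and 101 lower in low oxygen, about 129.8 by chance), and the random-block fit called 0 with 393. The unnamed genes with the smallest p were probe_3609 (0.87 ± 0.10) and probe_915 (0.84 ± 0.11) upward and probe_817 (-1.22 ± 0.10) and probe_1575 (-1.25 ± 0.12) downward, the last 2 near background on all 8 arrays. The sign was the same in all 4 single-orientation estimates for 444 genes, where about 324.4 would be by chance if genes and estimates were independent. Across all genes the oxygen effects in light and in dark correlated at 0.05, and among the 1297 genes above the median brightness at 0.28, but at -0.11 and -0.02 with median centring and at -0.37 and -0.14 with the authors' table. Effects of positions next to each other on the array correlated at 0.40. The arrays of high oxygen carry the numbers 4796 to 4799 and those of low oxygen 4800 to 4802 and 5876, so oxygen and the order of the arrays cannot be told apart.

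**Figure D2:**
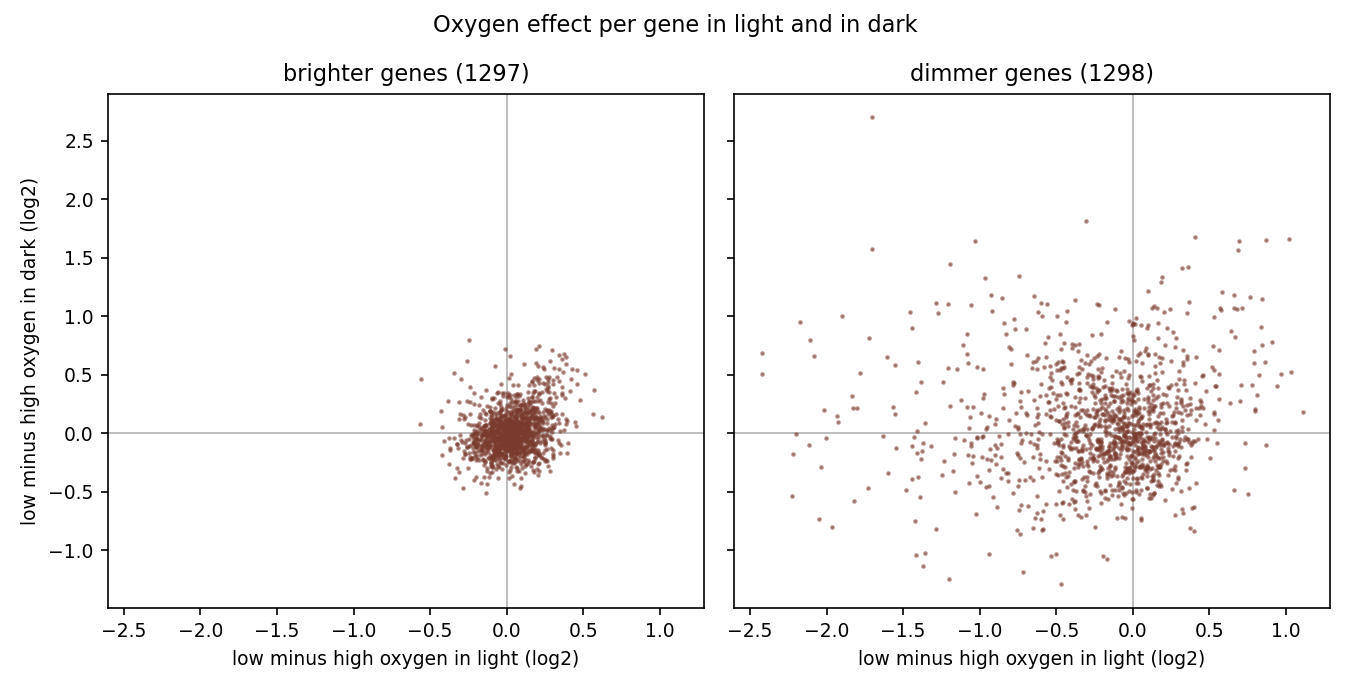
Low minus high oxygen effect of each gene (log2) in light (horizontal axis) and in dark (vertical axis), for the 1297 brighter genes at left and the 1298 dimmer genes at right; each point is 1 gene. The correlation is 0.28 at left and 0.05 at right, and the dimmer genes spread much further; with median centring the correlation of the brighter genes is -0.02 and with the authors' table -0.14.

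For dark against light, trpC of tryptophan synthesis had the highest value among named genes, 0.48 ± 0.11 (0.54 in high and 0.42 in low oxygen), and trpB of the same pathway had 0.25 ± 0.10. The values were 0.39 ± 0.11 for mutL, 0.17 ± 0.11 for aspS and 0.16 ± 0.12 for cysS, both aminoacyl-tRNA synthetase genes. Downward, hisD of histidine synthesis had -0.40 ± 0.10, mamA -0.49 ± 0.22 (near background on 7 arrays), orc7 -0.20 ± 0.10, carB -0.19 ± 0.10 and bat -0.26 ± 0.18. None was called (adjusted p from 0.958 to 0.998), and with the median of each block row removed trpC stood at 0.16, trpB at 0.12, carB at -0.02 and hop at -0.01. The light-related gene hop had 0.07 ± 0.10, and arcA, arcC and pyrF had 0.04 ± 0.10, 0.04 ± 0.12 and 0.14 ± 0.14. The value of bat came from high oxygen alone, with -0.52 there and 0.00 in low oxygen, a difference that was not tested.

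The rhodopsins and their transducers had a median of 0.03 in dark over light, with 4 of 5 genes above 0, and the halobacterial transducers a median of -0.07, with 2 of 7 above 0. In purine synthesis 1 of 7 lay above 0 (median -0.04), in pyrimidine synthesis 2 of 5 (median -0.01), in the TCA cycle 2 of 6 (median -0.02), and in chemotaxis 2 of 4 (median -0.01). DNA repair (median 0.01), cobalamin synthesis (median 0.02) and the chaperones and proteasome (median 0.02) each had 2 of 4 genes above 0. With median centring the medians of the TCA cycle (0.08), pyrimidine synthesis (0.08) and chemotaxis (0.09) lay above 0 and that of DNA repair (-0.07) below it. In that setting 3 of 4 chaperone and proteasome genes (median 0.25) and 4 of 4 cobalamin genes (median 0.21) also lay above 0. Only 1 of 4 chaperone and proteasome genes did with the authors' table (median -0.09), print-tip loess (-0.02) and block-row medians removed (-0.03). All 9 lists had a camera adjusted p of 0.919, and 0.967 as adjusted p with an estimated correlation. limma called 0 of 2595 genes, with 124 at an unadjusted p below 0.05 (47 higher and 77 lower in dark, about 129.8 by chance), and the random-block fit called 0 with 245. The smallest p belonged to unnamed genes, probe_3541 (0.63 ± 0.10) and probe_5319 (0.59 ± 0.10) upward and probe_5153 (-1.04 ± 0.10) and probe_1617 (-1.67 ± 0.17) downward, all near background on all 8 arrays. With the authors' table probe_5319 was called, at 1.21 (adjusted p = 0.0175, against up to 1 among the other settings). The sign was the same in 4 of 4 single-orientation estimates for 251 genes, below the 324.4 by chance, and the effects in high and low oxygen correlated at -0.02 across genes.

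**Figure D3:**
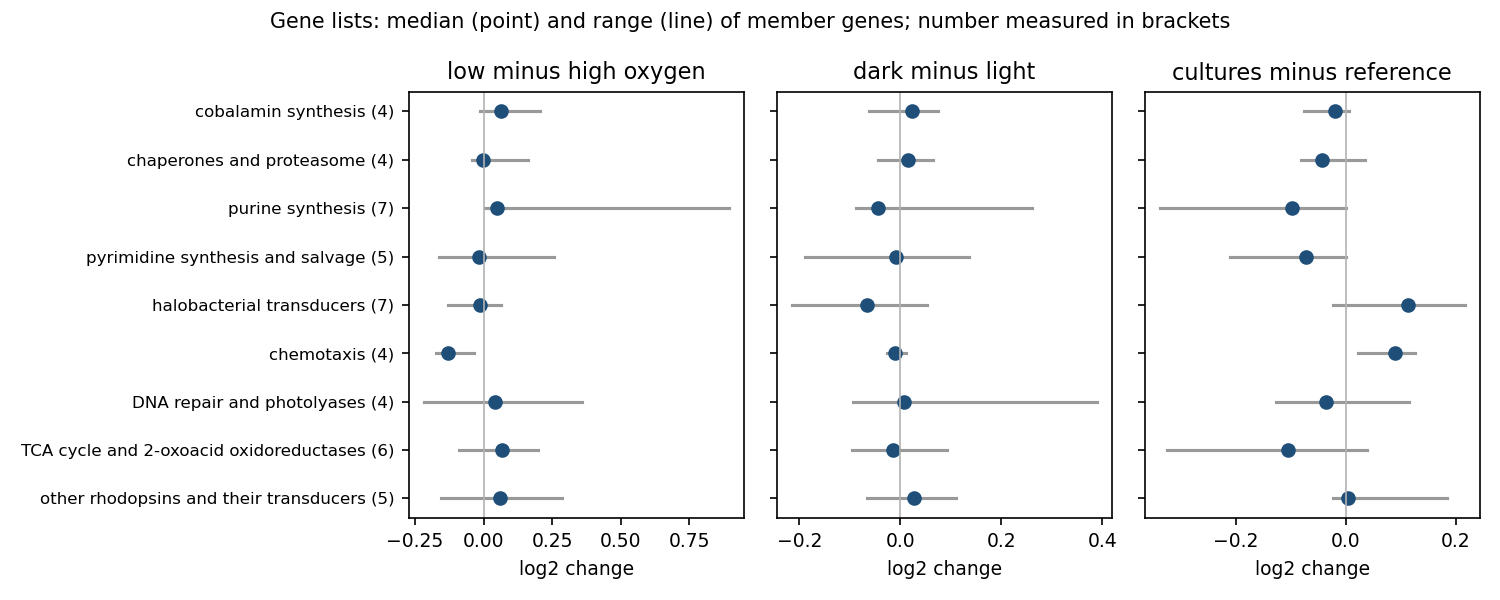
Median (point) and range (line) of the log2 changes of the member genes of 9 gene lists, for low minus high oxygen, dark minus light and cultures minus reference; the number of measured genes is in brackets and each panel has its own horizontal scale. No list passed its test, and the chemotaxis genes lie below 0 for oxygen (median -0.13) and above 0 against the reference (median 0.09).

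Whether the response to oxygen depended on light has no test with 1 RNA sample per condition. The oxygen effect in dark minus that in light had a median absolute size of 0.19, or 0.31 with median centring. Measured on the arrays with the sample in Alexa 532 it was 0.31 and on those in Alexa 647 0.28, and the orientations correlated at -0.04 across the 1297 brighter genes. Of these genes 612 had 1 sign in both orientations, fewer than had opposite signs, so the same sign in both is no evidence of replication. Among brighter named genes whose dye orientations had the same sign, the largest differences were positive for mvk, mevalonate kinase (0.47), argH, argininosuccinate lyase (0.40, saturated on 7 arrays), serB of serine synthesis (0.31) and purL (0.30), and negative for pheA (-0.45), htr6 (-0.39), speB (-0.33) and orc8 (-0.32). Of unnamed genes, probe_119 had 1.04, probe_2787 had 1.02, probe_1177 had -0.60 and probe_5201 had -0.56.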

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

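The tests of dye bias, dye orientation, array position and the pyrF signal were chosen only after the results they bear on had been seen.

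The activator gene bat had a ratio to the reference of 0.52 in high oxygen and light, against -0.01 to 0.00 in the other 3 samples. This gap was 0.97 of the whole range, above the critical value of 0.829 for 4 samples. It was 1 of 57 genes looked at, where chance gives about 1 in 20, and its spots were near background on 7 arrays. Other named genes near background on 7 or 8 arrays also had high ratios in high oxygen and light. The values were 0.82 for hutU, 0.74 for nadA and for nadC, 0.58 for gatC, 0.57 for mamA and 0.40 for hutI. A high ratio in this sample was thus not particular to bat, though purB (-0.57) and hutG (-0.22), near background on 8 arrays, lay below 0. Replicate 1 of this sample stands apart from the other arrays, and the SD of bat over both arrays was 0.08 in this sample, 0.11 in high oxygen and dark, 0.55 in low oxygen and light and 0.81 in low oxygen and dark, so the close values of the other samples rest partly on arrays that differ by more than the gap.

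For 12 of the 18 genes named for the interaction, the oxygen effect had one sign in light and the opposite sign in dark, in both dye orientations. The genes had been picked for large differences of the same sign in both orientations, which makes this outcome likely. The difference was not tested. Among named genes the oxygen effect in dark minus that in light was 0.47 for mvk, 0.31 for serB, -0.33 for speB and -0.32 for orc8. Among unnamed genes it was 1.04 for probe_119, 1.02 for probe_2787, -0.60 for probe_1177 and -0.56 for probe_5201. For 4 others it was 0.88 (probe_113), 0.86 (probe_251), 0.76 (probe_117) and -0.55 (probe_5203). By number, probe_113, probe_117 and probe_119 lie close together on the array, and probe_5201 and probe_5203 next to each other. Their values may share an effect of position, which was not tested. Interactions of positions next to each other correlated at 0.19.

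Opposite-dye arrays of the same RNA sample disagreed after turning. Replicate spots of the same array correlated across genes at 0.19 (low oxygen in dark, replicate 2) to 0.63 (high oxygen in light, replicate 1). Low agreement within an array may limit the agreement between arrays, and its part in the disagreement was not tested. The labelled orientation separated the unturned ratios better than any other of the 35 splits of the 8 arrays into 4 and 4, since 1 split, the labelled one, reached its difference in correlation of 0.13 and the highest other reached 0.08. With the dye of a single array exchanged the difference reached 0.14 (margin of the labels over the best exchange -0.01, block bootstrap 95% interval -0.05 to 0.02), so a single wrong label stays open, and an exchange of all labels would leave these values as they are and was not tested. The dye effects of different RNA samples correlated across genes at 0.27 on average, from 0.46 to 0.57 among the 3 pairs without high oxygen in light and from -0.09 to 0.20 with it, so a dye bias specific to genes and shared by all samples stays open. No biological explanation was tested, as the dye flips share their RNA.

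The oxygen effects of brighter genes correlated at 0.28 between light and dark (block bootstrap 95% interval 0.18 to 0.37). The correlation was 0.22 (0.05 to 0.34) among the 508 genes without a saturated spot, 0.29 (0.19 to 0.37) after a trend with brightness was removed, and 0.22 (0.16 to 0.28) after the medians of block rows were removed. It was 0.30 after a smooth position trend was removed, which left most of the correlation between neighbouring positions. The uncorrected interval already reached below 0.2, the bound set for excluding an explanation, so this rule could hardly exclude any. Removal of the brightness trend did not lower the correlation. The main normalization had already removed such a trend within each array, so this test had little left to remove and cannot decide. A trend with brightness, saturation and position stay open as part of the correlation. Under median centring the correlation was -0.02 and with the authors' table -0.14, and over all genes the 0.05 turned to -0.11 with block-row medians removed, -0.11 with median centring and -0.37 with the authors' table. A shared response to oxygen also stays open, untested, and it may be confounded with the order of the arrays.

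The pyrF ratio was not clearly lower in the deletion strain. The log2 of spot over local background averaged 0.98 in Alexa 532 and 1.28 in Alexa 647, above the 95th percentile of 93 blank positions (0.52 and 0.89), which argues against a probe with blank signal only. The 95% interval of the ratio, from the limma SE over the 4 samples, ran from -0.31 to 0.13. It does not take in the spread of dye flips, which read 0.67 and -0.77 in high oxygen and light. No size of loss was named in advance and the ratios may be compressed, so the interval alone does not exclude a loss. A probe outside the deleted part, or signal from other transcripts, may account for the pyrF ratio and could not be tested.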

How the results depend on the processing

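Added after the data had been seen were the low-setting ratios, the set of brighter genes without a saturated spot, the removal of block-row medians and the leave-one-out fits with the dye effect removed. No paired analysis was possible because the replicate numbers name dye orientations of the same RNA and the labels give none. Only the lists fixed in advance were tested under these settings. No setting called a gene for oxygen, or any of these lists for oxygen or light. For dark versus light the authors' table called 1 gene. With that table limma gave different genes the same SE (0.27 for oxygen and 0.13 against the reference). Its calls therefore rest on a variance pooled over genes. Against the reference, 1 gene was called with no background correction, with 8 arrays in a random block and with the authors' table, and 0 to 1 when arrays were left out. Of the lists fixed in advance, those called against the reference numbered 1 with median centring and with the authors' table (TCA cycle). They numbered 1 in brighter genes without a saturated spot (transducers), and 2 (TCA cycle and purine synthesis) without low-confidence spots, with the random block, at an adjusted p below 0.10 and with block-row medians removed. When arrays were left out they numbered 0 to 1. Lists added later are not counted here, though some had a camera adjusted p below 0.10 in the main fit. With an estimated correlation 0 lists were called in any of these settings (smallest adjusted p from 0.486 to 0.94), except that the random block was not run this way. On 1 residual degree of freedom that variant could hardly call a list, so it does not weigh against these calls. The single list called by leaving out an array was purine synthesis, without replicate 1 of high oxygen in light (adjusted p = 0.0276); over all settings the smallest adjusted p of a list against the reference ranged from 0.0208 to 0.204. The median absolute interaction moved from 0.19 to 0.14 with no background correction and to 0.31 with median centring. The cause was not tested for any of these. Uncalled genes changed sign as follows. Median centring gave arcA -0.0724 in dark versus light and arcC -0.0219 against the reference, print-tip loess gave pyrF 0.0909 for oxygen, and the authors' table gave 0.0374 and 0.021 for 2 unnamed genes, 0.176 for pyrF and -0.0413 for arcA for oxygen, and 0.0407 for pyrF against the reference. Removal of block-row medians gave arcC 0.0562 for oxygen and hop -0.0058 in dark versus light. With arrays left out, with or without the dye effect, pyrF ranged from -0.41 to 0.31 for oxygen, from -0.22 to 0.50 for light and from -0.27 to 0.0883 against the reference, and bat from -0.56 to 0.0139, from -0.55 to 0.0276 and from -0.0183 to 0.27. For light, arcA ranged from -0.0554 to 0.13, arcC from -0.12 to 0.19, hop from -0.0161 to 0.16 and cysS from -0.0253 to 0.34, and arcA against the reference from -0.017 to 0.0746. For oxygen, arcC ranged from -0.36 to -0.05 and arcA from 0.03 to 0.21. Of the values of genes picked for the text, with or without a symbol, 18 of 568 had the opposite sign with an array left out. The count was 12 of 568 with the dye effect also removed and 10 of 903 under the other settings. Moves of more than 1 SE of the main fit numbered 216, 200 and 180 in the same order. Leaving out 1 array leaves its sample with 1 dye orientation, so these fits also carry dye bias and assume that this sample varies like the others. Spots at or below background, 2.67% to 9.44% per array, limit dim genes.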

Other observations

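The tests here were chosen after the gene names or the values had been seen. Of 7 lists written after the gene names were known, none passed. Against the reference 11 of 14 genes of aminoacyl-tRNA synthetases and amidotransferase, 5 of 6 of histidine synthesis, 3 of 4 of glutamate and glutamine metabolism and 3 of 4 of DNA gyrase and replication origin proteins lay below 0, each with a camera adjusted p of 0.0698, and 0.421 with an estimated correlation. Medians were -0.07, -0.11, -0.13 and -0.15. These lists too hold named genes only, so their values cannot be told apart from a difference of the named genes as a set. In the glutamate list 1 gene was called adjusted over the list alone. All 3 thiamine genes lay below 0 (median -0.13, adjusted p = 0.0734), while histidine utilization (median 0.18, adjusted p = 0.811) and protein export (median -0.02, adjusted p = 0.831) did not share a direction. All 6 histidine synthesis genes lay below 0 in dark versus light (median -0.08, adjusted p = 0.521), but 4 of 6 with the authors' table and 5 of 6 with print-tip loess or block-row medians removed. For oxygen the 7 lists had adjusted p of 0.989.

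Neighbouring positions correlated at 0.40 for oxygen, 0.28 for light, 0.17 against the reference and 0.19 for the interaction. Related genes can lie close together, such as hutI and hutU at first probes 3059 and 3067. An effect of position and a shared response of such genes therefore cannot be told apart. Positions 256 probe numbers apart correlated at -0.03 for oxygen. Removing block-row medians brought the first of these to 0.00, but left 0.11 for oxygen and 0.08 for light between positions 64 probe numbers apart (0.26 and 0.17 before), and smooth trends over the array left the correlation of neighbours for oxygen at 0.35, 0.32 and 0.30 with spans of 0.05, 0.02 and 0.01.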
